A study of Drosophila melanogaster with 17 samples.

How the data were processed

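Eye discs of Drosophila larvae at the 3rd instar were profiled on the Affymetrix Drosophila Genome 2.0 array from 50 ng of total RNA per sample, per the labels. The 6 groups were wild type, dDP mutant and de2f1 (E2f1 removed from the posterior of the disc), each untreated or irradiated, with 3 biological replicates per group and 2 for irradiated wild type discs, whose sample number 2 was not analysed here. The deposited values are log2 summaries per probe set made with RMA, per the submitters' processing notes, and the RMA version is not given in the sources used here. The table holds 18952 probe sets on 17 arrays. Array medians lay between 5.82 and 5.99, and the values were used without further scaling. The 183 control probe sets were left out of the tests and used to compare 3-prime with 5-prime signals of actin, GAPDH and eIF-4a, which left 18769 tested. Median standard deviations within groups were 0.0637 to 0.114 on the log2 scale.

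Of the tested probe sets 13647 carried 1 gene symbol, 402 carried several and 4720 none. Named genes and gene lists used probe sets with 1 symbol, 11982 genes in all, and for the 1094 genes with several such probe sets the one with the highest mean over all arrays. E2f1, rpr, hid, Xrp1 and RnrS have no such probe set and were not analysed here.

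A linear model with 1 mean per group was fitted to each probe set over all arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an untrended, non-robust prior of 2.56 degrees of freedom and prior SD 0.0935). Contrasts were irradiated against untreated within each genotype, each mutant against wild type and dDP against de2f1 in untreated discs, each mutant against wild type in irradiated discs, and the 3 differences of the irradiation effect between genotypes. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets of a contrast were called changed, and the errors given are standard errors of the contrast from the moderated fit. Gene lists, fixed by name, were tested with camera (preset correlation 0.01, then the estimated correlation) and fry, adjusted over the lists within a contrast, and members were also adjusted over their list alone. The design, the lists, the rule for naming genes and most alternatives were set before the data were examined. Exceptions are the ring gland list and 4 alternatives, the respiratory chain list without paralogs among them, made after the values were seen.

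Genes were named by rule in each contrast: fixed genes of interest (Dp, skl, grim, Corp, PCNA and CycE among those measured) whatever their result, up to 8 called genes per direction with the largest change whose arrays do not overlap between the groups (no such condition for differences of irradiation effects), and up to 4 called members of each list with the smallest adjusted p. Among these, the text mostly names genes whose call held with any 1 array left out, a choice made after the values were seen, and says where it did not. Genes named for a difference of irradiation effects were also looked up in the 3 irradiation contrasts. dysf and ftz-f1 were named outside this rule.

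The part of the wild type response seen in a mutant was the slope through the origin of the mutant on the wild type change. Overlap of the mutants was set beside the number independence gives and beside 50 simulations of unchanged mutants sharing the wild type arrays. The alternatives were a trended or robust prior, array weights, leaving out the 40% dimmest probe sets, 1 probe set per gene, quantile normalization, fitting the arrays of a contrast alone, the replicate number as a block and leaving out each array in turn, with fry, the estimated correlation, the most variable and every probe set for lists, and those added later. Other splits of the samples were drawn with a fixed seed. Simulated code tests shifted 50 probe sets each by log2 0.5, 1, 2 and 3. At log2 1, 94% were recovered in wild type discs and 90% for the dDP to wild type difference, with 11 and 7 false calls in all. Annotation, figures and tables used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.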

Results

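Loss of Dp, the partner protein that E2F transcription factors need to bind DNA, and removal of E2f1 from the posterior of the eye disc were compared with wild type in Drosophila larvae. Discs were left untreated or collected 4 h after 40 Gy of gamma radiation, with 3 biological replicates per group except for irradiated wild type discs, which had 2 (numbers 1 and 3). The dDP discs carried a reduced Dp signal on every array. Dp read log2 8.06 to 8.94 on the 3 untreated and 8.25 to 8.88 on the 3 irradiated dDP arrays, against 10.37 to 10.42 and 10.04 to 10.23 in wild type and 10.30 to 10.50 and 10.12 to 10.30 in de2f1 discs. The fall was -1.96 ± 0.19 in untreated and -1.53 ± 0.21 in irradiated discs relative to wild type (limma, Benjamini-Hochberg adjusted p = 2.5e-06 and 9.3e-05, n = 3 against 3 and 3 against 2). Dp did not pass in de2f1 discs (0.03, adjusted p = 0.965). Where the probes lie relative to the dDP lesion is not given in the sources used here. E2f1 shares its probe set with Torsin, so its own level was not analysed here.

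Among the 17 arrays, log2 values ran from 3.25 to 14.77, and the first principal component held 42.8% of the variance. Correlation with the other arrays of the same group averaged from 0.983 (dDP untreated array 1) to 0.997. Actin control probe sets at the 3-prime end exceeded those at the 5-prime end by log2 3.05 and 3.26 on dDP untreated arrays 2 and 3, against 1.69 to 2.28 on the other 15. RNA integrity was not analysed here. Marker genes of the salivary gland averaged log2 5.72 to 6.04 in untreated dDP discs, 6.45, 12.72 and 13.05 in the irradiated dDP discs, 6.43 in de2f1 untreated disc sample 1 and 10.08 to 12.85 on all remaining arrays. Fat body markers averaged 11.36 on dDP untreated array 1 and 7.23 to 10.20 elsewhere. Lower quartiles of the arrays lay at 4.51 to 4.60. A group mean below 4.60 is called near the floor here, and a difference from such a group is a lower bound. The p values below measure the spread between these samples.

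Irradiation raised DNA damage response genes in wild type discs. The alkyl-repair gene agt rose by log2 2.62 ± 0.12, the p53 target Corp by 2.41 ± 0.26 and the TNF ligand gene egr by 1.79 ± 0.09 (n = 2 irradiated against 3 untreated). Genes of the cell cycle moved the other way: the replication licensing gene dup fell by -0.75 ± 0.06 and the mitotic kinase gene aurB by -0.67 ± 0.07. Other large rises that held whichever array was left out were those of AOX1 (3.12 ± 0.26), amd (2.52 ± 0.18), CG3448 (2.34 ± 0.22), rdog (2.26 ± 0.33) and Ugt302K1 (2.16 ± 0.10). Large falls of this kind were those of Osi4 (-2.09 ± 0.11), CG8483 (-1.36 ± 0.12), CG3880 (-1.28 ± 0.11) and CG13064 (-1.19 ± 0.15) (limma, Benjamini-Hochberg adjusted p of 3.0e-08 to 7.3e-04). In total 846 of 18769 probe sets changed, 486 rising and 360 falling, with 104 rises and 14 falls beyond 2-fold. Without wild type irradiated array 1 or 3 the number was 526 or 389, and it was 1317 with array weights.

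The fixed list of radiation response genes had 11 of 14 members rising in wild type discs (11 adjusted over the list alone) with a median log2 change of 1.35. Its camera adjusted p was 9.2e-24, and adjusted p = 0.0617 with an estimated correlation. Its members mre11 (1.92 ± 0.09) and Ku80 (2.00 ± 0.13), both coding for DNA break repair proteins, rose. Of the radiation response genes p53 rose by 0.91 ± 0.15. Among 42 repair and checkpoint genes 17 rose and 3 fell (18 and 7 over the list alone), rad50 rising by 1.39 ± 0.08. The repair and checkpoint list had camera adjusted p = 2.0e-08 and adjusted p = 0.302 with an estimated correlation. The initiator caspase gene Dronc rose by 0.75 ± 0.07 as 1 of 5 cell death genes that rose among 18. Their median was -0.02 although the mean (0.29) and the camera direction were positive (adjusted p = 0.069). The call passed without wild type untreated array 1 or 2 or irradiated array 3 (adjusted p = 0.0382, 0.0389 and 0.0122, over its alternatives 8.0e-05 to 0.231). Without untreated array 1 or 2 the median was 0.02 or 0.03. JNK and injury genes had 5 of 15 members rising (5 over the list alone), such as scaf (1.16 ± 0.10), Jra (0.64 ± 0.06) and puc (0.64 ± 0.08). The JNK and injury list gave camera adjusted p = 1.2e-06 and adjusted p = 0.0884 with an estimated correlation. The germline genes spn-E (1.82 ± 0.09) and orb (1.50 ± 0.15) also rose, while their list did not pass (camera adjusted p = 0.847, median -0.02 and mean 0.10).

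S phase genes of the E2F-activated type fell in irradiated wild type discs: 19 of 41 fell and 2 rose (26 and 2 over the list alone), with median -0.31. Camera gave adjusted p = 2.9e-18 for the list, and adjusted p = 0.0884 with an estimated correlation. Thymidylate synthase gene Ts fell by -1.02 ± 0.10 and the DNA polymerase gene PolE2 by -0.70 ± 0.06, whereas RnrL, coding for the large ribonucleotide reductase subunit, rose by 0.83 ± 0.07. PCNA fell by -0.30 ± 0.06 (limma adjusted p = 0.00563), a call lost without wild type irradiated array 3 (adjusted p = 0.0937) and with the 5 wild type arrays fitted alone (0.055, over its alternatives 6.2e-04 to 0.0937). Of 37 G2 and M phase genes 17 fell and 1 rose (24 and 1 over the list alone), including the chromosome segregation genes Incenp (-0.52 ± 0.07), Nuf2 (-0.51 ± 0.06) and fzy (-0.44 ± 0.06). The G2 and M phase list gave camera adjusted p = 3.9e-16 and adjusted p = 0.0884 with an estimated correlation. Ribosome biogenesis genes had a median of 0.18, with 2 of 17 rising over all genes and 15 over the list alone. The ribosome biogenesis list had camera adjusted p = 6.0e-09 and adjusted p = 0.0953 with an estimated correlation. Detoxification genes, among them GstD1 (0.47 ± 0.05), had 4 of 23 rising (6 over the list alone) and a median of 0.19. The detoxification list gave camera adjusted p = 4.0e-04 and adjusted p = 0.328 with an estimated correlation. CycE (-0.08), skl (-0.20), grim (-0.05) and Dp (-0.25) did not pass (adjusted p of 0.707 to 0.959). No member passed among the markers of salivary gland, fat body or hemocytes (limma; 0, 0 and 4 at an unadjusted p under 0.05), though the hemocyte list passed camera without wild type untreated array 2 (adjusted p = 0.0371 against 0.208, over its alternatives 0.0371 to 0.854).

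**Figure D1:**
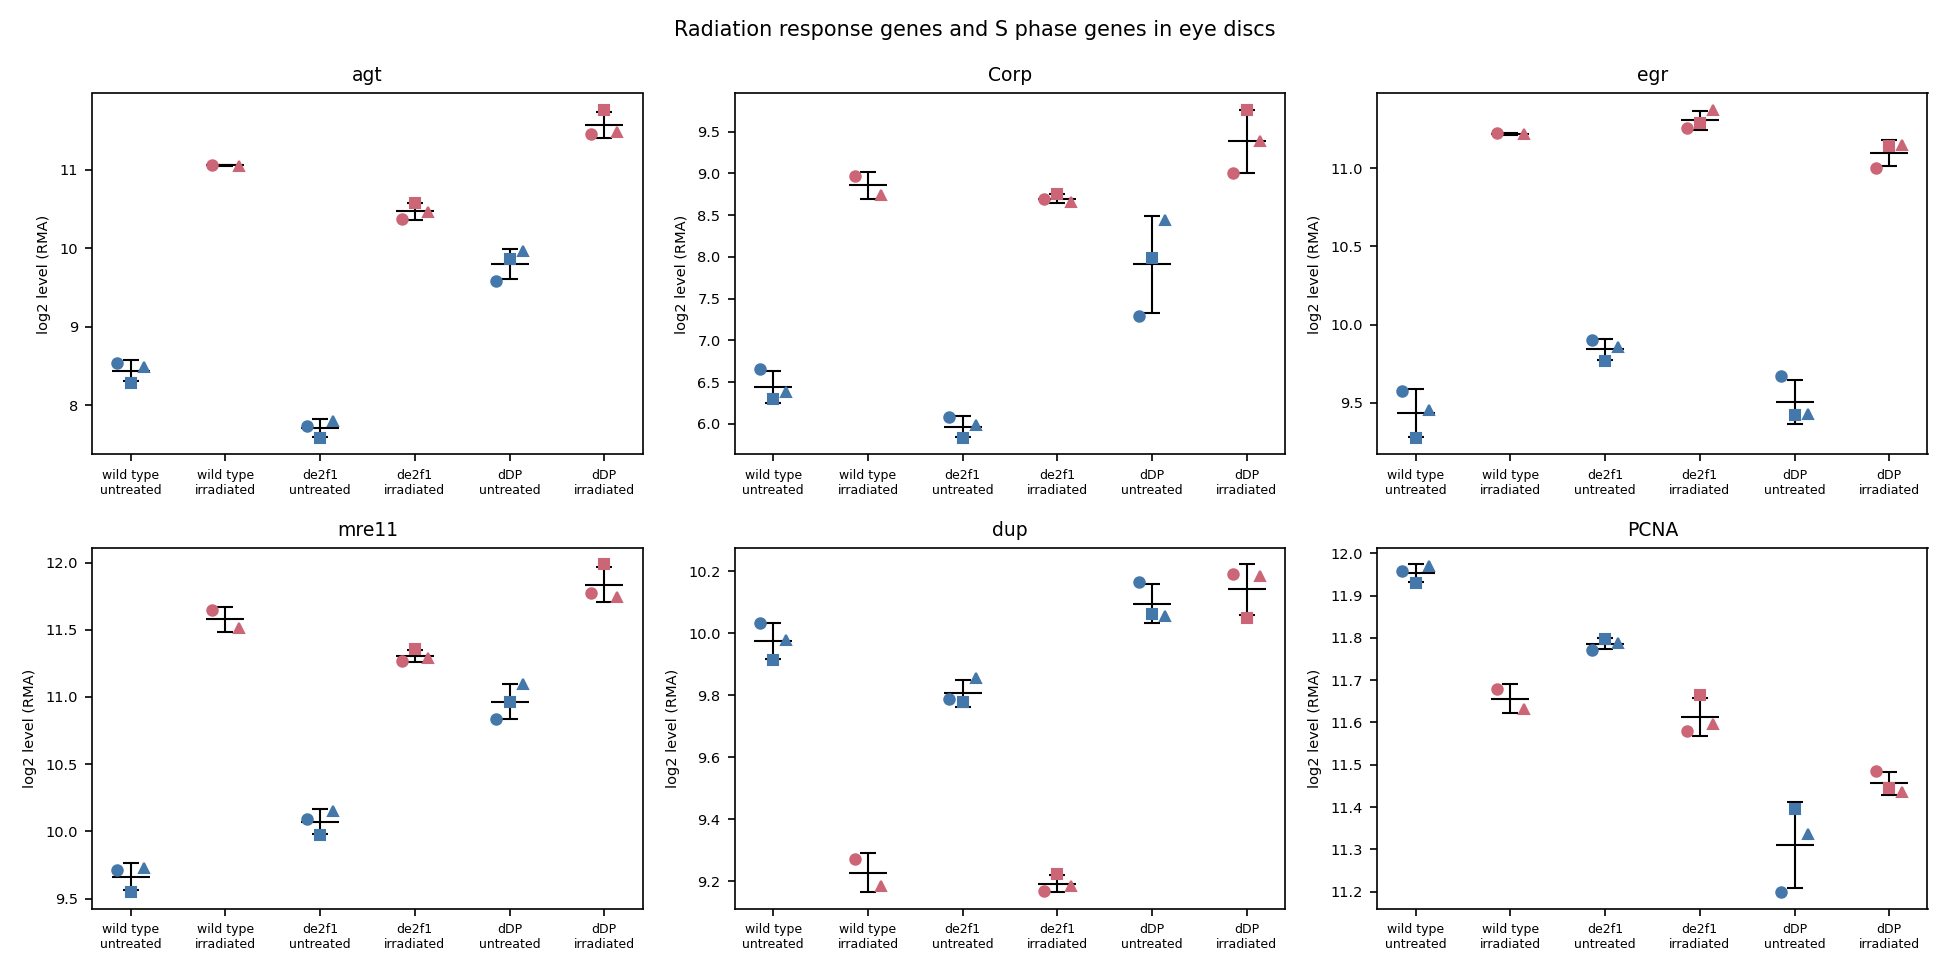
Log2 levels (RMA) of 6 genes on each array (points, shape by replicate number) with the group mean ± SD (bars) for wild type, de2f1 and dDP discs, untreated and irradiated. agt rose by 2.62, 2.76 and 1.77 in wild type, de2f1 and dDP discs, while dup fell by -0.75 and -0.61 in the first 2 and did not pass in dDP discs (0.05).

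In de2f1 discs irradiation also raised damage response genes. There agt (2.76 ± 0.11), Corp (2.74 ± 0.23) and egr (1.47 ± 0.08) rose (n = 3 against 3), and the licensing gene dup fell by -0.61 ± 0.05. Further large rises that held with any 1 array left out were those of AOX1 (2.36 ± 0.23), Rchy1 (2.20 ± 0.07), rdog (1.98 ± 0.30), CG14695 (1.93 ± 0.13), spn-E (1.87 ± 0.08) and CG15784 (1.85 ± 0.18). Such falls included Osi4 (-1.69 ± 0.10), CG13840 (-1.54 ± 0.17), LManI (-1.13 ± 0.19), CG13064 (-0.96 ± 0.14) and CG3880 (-0.83 ± 0.10) (limma, Benjamini-Hochberg adjusted p of 8.9e-10 to 0.00462). Altogether 431 probe sets changed, 257 rising and 174 falling, and 268 passed without de2f1 irradiated array 3. Array weights raised the number to 1039.

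Radiation response genes rose in 11 of 14 cases in de2f1 discs (11 over the list alone), with median 1.03. The radiation response list had camera adjusted p = 1.7e-30 and adjusted p = 0.0236 with an estimated correlation. The DNA end-binding gene Irbp rose by 1.78 ± 0.13, mre11 by 1.23 ± 0.08 and p53 by 0.90 ± 0.14. Among 42 repair and checkpoint genes 13 rose (16 over the list alone), rad50 by 1.00 ± 0.07. The repair and checkpoint list had camera adjusted p = 6.7e-12 and adjusted p = 0.199 with an estimated correlation. Cell death genes rose in 6 of 18 cases and fell in 1, Dronc by 0.63 ± 0.06. The cell death list had a median of 0.05, camera adjusted p = 0.00206 and adjusted p = 0.0651 with an estimated correlation. That median turned to -8.0e-04 without de2f1 irradiated array 2. JNK and injury genes rose in 6 of 15 cases (7 over the list alone), with scaf (1.06 ± 0.09), puc (0.63 ± 0.08) and Jra (0.51 ± 0.05). The JNK and injury list had camera adjusted p = 1.6e-10 and adjusted p = 0.0236 with an estimated correlation. orb rose by 1.36 ± 0.13, GstD1 by 0.32 ± 0.05 and mRpL30 by 0.37 ± 0.06.

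As a list, S phase genes fell in de2f1 discs too: 13 of 41 members fell and 2 rose (23 and 2 over the list alone), median -0.20. The S phase list had camera adjusted p = 2.8e-13 and adjusted p = 0.171 with an estimated correlation. The polymerase gene PolE2 fell by -0.54 ± 0.06 and the helicase gene Mcm5 by -0.54 ± 0.06, RnrL rose by 0.57 ± 0.06, and PCNA did not pass (-0.17, limma adjusted p = 0.116) except with array weights (0.0116, over its alternatives 0.0116 to 0.352). Of the G2 and M phase genes 3 of 37 fell (7 over the list alone), the centromere histone gene cid by -0.55 ± 0.09, with a list median of -0.07. The G2 and M phase list gave camera adjusted p = 1.7e-04 and adjusted p = 0.494 with an estimated correlation and 0.0639 with fry, over its alternatives 1.3e-05 to 0.494. The pyruvate carrier gene Mpc1 fell by -0.57 ± 0.07. CycE, skl, grim and Dp again did not pass (0.00, -0.04, -0.11 and -0.21, limma adjusted p of 0.521 to 1). Hemocyte markers had a median of -0.66 with 1 of 13 falling (4 over the list alone). The hemocyte list gave camera adjusted p = 1.7e-04 and adjusted p = 0.425 with an estimated correlation and 0.0569 with fry, over its alternatives 5.9e-08 to 0.425.

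Damage response genes also rose in irradiated dDP discs, where S phase genes did not fall as a list. agt rose by 1.77 ± 0.11, Corp by 1.48 ± 0.23 and egr by 1.59 ± 0.08 (n = 3 against 3), while dup (0.05 ± 0.05) and PCNA (0.15 ± 0.05) did not pass (limma, Benjamini-Hochberg adjusted p = 0.664 and 0.0905). PCNA passed as higher without dDP untreated arrays 2 and 3 (0.26, adjusted p = 0.0151) and with the actin difference as a covariate (0.21, adjusted p = 0.0306, over its alternatives 0.0151 to 0.4). Large rises that held with any 1 array left out included CG17047 (2.37 ± 0.48), Cyp6d2 (2.09 ± 0.12), AOX1 (2.05 ± 0.23), CG14695 (1.91 ± 0.13), Snap25 (1.82 ± 0.33), Osi14 (1.70 ± 0.27) and Ugt302K1 (1.70 ± 0.09). Such falls included the cuticle gene Cpr72Ea (-1.75 ± 0.32), CG3355 (-1.52 ± 0.27), CG11125 (-1.11 ± 0.09) and CG5250 (-1.07 ± 0.09) and the cytochrome P450 gene Cyp6w1 (-1.03 ± 0.19). With the 6 dDP arrays fitted alone Corp, CG17047, Osi14, Cpr72Ea, CG3355 and Cyp6w1 did not pass (adjusted p of 0.101 to 0.14, over their alternatives 4.1e-05 to 0.158). CG3355 did not pass without untreated arrays 2 and 3 together either (-1.01, adjusted p = 0.158, over its alternatives 3.6e-04 to 0.158). Of 1659 changed probe sets 836 rose and 823 fell (802 and 1054 after quantile normalization and 1672 and 2177 without dDP untreated array 1), with 79 and 10 beyond 2-fold. The number hung on single arrays: 962 without dDP untreated array 3, 980 without dDP untreated array 2, 1072 without dDP irradiated array 2 and 3849 without dDP untreated array 1. It was 678 with the salivary score as a covariate, 242 with the 6 dDP arrays fitted alone and 3851 with array weights.

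Of 14 radiation response genes 11 rose in dDP discs (11 over the list alone), with median 0.96. The radiation response list had camera adjusted p = 2.8e-16 and adjusted p = 0.104 with an estimated correlation. The excision repair gene Xpc rose by 0.60 ± 0.05 and the end-joining gene Ku80 by 1.32 ± 0.12. Repair and checkpoint genes rose in 16 of 42 cases and fell in 1 (19 and 2 over the list alone), the single-strand binding gene RPA1 by 1.22 ± 0.09. The repair and checkpoint list had camera adjusted p = 1.3e-08 and adjusted p = 0.463 with an estimated correlation. Cell death genes rose in 7 of 18 cases and fell in 2, the rises including Dronc (0.97 ± 0.06) and its activator Dark (0.57 ± 0.06). The cell death list gave camera adjusted p = 0.00203 and adjusted p = 0.104 with an estimated correlation. Among JNK and injury genes 5 of 15 rose, with scaf (0.62 ± 0.09), puc (0.45 ± 0.08) and Jra (0.38 ± 0.05). These 3 did not pass with the 6 dDP arrays fitted alone (limma adjusted p of 0.0592 to 0.102, over their alternatives 5.8e-05 to 0.102). The JNK and injury list had camera adjusted p = 4.3e-06 and adjusted p = 0.109 with an estimated correlation. The germline genes orb (1.02 ± 0.13) and spn-E (0.80 ± 0.08) rose as well.

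S phase genes in dDP discs split evenly, with 4 of 41 rising and 4 falling (6 and 9 over the list alone) and a median of -0.03 (camera adjusted p = 0.777). RnrL (1.04 ± 0.06), dnk (0.44 ± 0.08) and the clamp loader gene RfC4 (0.53 ± 0.06) rose, and RfC3, of the same complex, fell by -0.97 ± 0.11. G2 and M phase genes fell in 11 of 37 cases (16 over the list alone), as in Nuf2 (-0.55 ± 0.05), Incenp (-0.47 ± 0.06), Klp61F (-0.35 ± 0.05) and Cap-D2 (-0.32 ± 0.05). Fitting the 6 dDP arrays alone left dnk, Incenp, Klp61F and Cap-D2 short of the threshold (limma adjusted p of 0.055 to 0.135, over their alternatives 2.3e-05 to 0.135). The G2 and M phase list gave camera adjusted p = 3.8e-06 and adjusted p = 0.51 with an estimated correlation. CycE, skl, grim and Dp did not pass (0.08, 0.45, 0.15 and 0.18, limma adjusted p of 0.144 to 0.655). Dp passed without dDP untreated array 1 (adjusted p = 0.047) and with array weights (0.0241, over its alternatives 0.00142 to 0.998). Without dDP untreated array 1 and irradiated array 2 together, Dp and CycE passed (0.00142 and 0.00361, over their alternatives 0.00142 to 0.998).

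Mitochondrial ribosomal genes fell as a group in irradiated dDP discs. Among 69 genes of the mitochondrial ribosome 30 fell and 2 rose (47 and 2 over the list alone), with median -0.19. The mitochondrial ribosomal list had camera adjusted p = 1.6e-12 and adjusted p = 0.572 with an estimated correlation. mRpL36 fell by -0.55 ± 0.07 and mRpL2 by -0.40 ± 0.05 (limma adjusted p = 2.3e-04 and 3.1e-04). Respiratory chain and ATP synthase genes fell in 18 of 77 cases and rose in 1 (26 and 2 over the list alone), the rise being COX7AL (0.80 ± 0.10). The respiratory chain list gave camera adjusted p = 3.8e-06 and adjusted p = 0.603 with an estimated correlation. The succinyl-CoA synthetase gene ScsbetaG fell by -0.33 ± 0.05 and the mitochondrial fusion gene Opa1 rose by 0.43 ± 0.06. When only the 6 dDP arrays were fitted, mRpL36, mRpL2, ScsbetaG and Opa1 did not pass (adjusted p of 0.0601 to 0.12, over their alternatives 7.6e-06 to 0.12). The same mitochondrial ribosomal genes had medians of -0.06 in wild type and -0.02 in de2f1 discs (camera adjusted p = 0.386 and 0.678). In wild type discs the respiratory chain median was -0.07 (camera adjusted p = 0.0303, adjusted p = 0.854 with an estimated correlation and 0.335 with fry). This call was lost without wild type untreated array 3 or irradiated array 1 (adjusted p = 0.201 and 0.144, over its alternatives 0.00848 to 0.854). For de2f1 discs it was -0.05 (camera adjusted p = 0.00584, adjusted p = 0.779 with an estimated correlation and 0.329 with fry), a call lost without de2f1 untreated array 3 (adjusted p = 0.244, over its alternatives 2.2e-04 to 0.779). The mitochondrial ribosomal fall in dDP discs differed between the untreated arrays it was measured against. Relative to array 1, where fat body markers averaged 11.36, the mitochondrial ribosomal median was -0.05. Relative to arrays 2 and 3, with their larger actin control differences, it was -0.26 and -0.25. With the actin difference of each array as a covariate it was -0.10 (camera adjusted p = 2.6e-05, over its alternatives 1.0e-18 to 0.572). Salivary gland markers averaged 12.72 and 13.05 in irradiated dDP samples 2 and 3, against 6.45 in irradiated sample 1 and 5.72 to 6.04 in the untreated ones. Over all 3 against 3 arrays the salivary list had a median change of 5.32, and no member passed (limma, 7 of 8 at an unadjusted p under 0.05, camera adjusted p = 9.1e-04, adjusted p = 0.572 with an estimated correlation and 0.0822 with fry, over its alternatives 1.4e-07 to 0.572).

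S phase genes responded differently to irradiation in dDP and wild type discs. The difference (dDP minus wild type) was 0.79 ± 0.08 for dup and 0.69 ± 0.08 for the replicative helicase gene dpa (limma interaction, Benjamini-Hochberg adjusted p = 9.9e-04 and 0.00143; dDP n = 3 and 3, wild type n = 2 and 3). For PCNA it was 0.44 ± 0.07 (adjusted p = 0.0244), a call that ended without any 1 of the 5 wild type or 3 irradiated dDP arrays (highest adjusted p = 0.183, over its alternatives 0.00184 to 0.24) after quantile normalization (0.0929) and with the replicate number as a block (0.078). In the S phase list 8 of 41 members responded higher in dDP discs (19 over the list alone, where 1 was lower), with a median difference of 0.32. The S phase list gave camera adjusted p = 1.2e-20 and adjusted p = 0.196 with an estimated correlation. Outside that list Osi4 (1.33 ± 0.15), timeout (0.81 ± 0.12) and CG9752 (0.74 ± 0.09) also responded higher in dDP discs. The response was lower in dDP discs for mre11 (-1.04 ± 0.12), spn-E (-1.02 ± 0.12), CG4962 (-2.10 ± 0.28), CG32313 (-1.41 ± 0.18) and CG5250 (-1.10 ± 0.13) (adjusted p of 0.0015 to 0.00405). Before irradiation mre11 already read 10.84 to 11.10 in dDP against 9.55 to 9.73 in wild type discs. After irradiation it read 11.75 to 11.99 against 11.51 to 11.64, so its smaller response went with a higher level. Untreated dDP discs also had a higher spn-E level than wild type discs. CG5250 did not pass in wild type discs (0.04, limma adjusted p = 0.95) and fell in dDP discs. Cyp6a17 was called too (-1.42 ± 0.18) but lay near the floor in untreated and irradiated dDP discs (4.41 and 4.32), so its response in those discs could not be measured. With the 11 arrays of the 2 genotypes alone CG4962 and PCNA did not pass (adjusted p = 0.0696 and 0.24, over their alternatives 0.00179 to 0.24). The radiation response list differed by a median of -0.31, with 1 of 14 members lower (7 over the list alone). The radiation response list had camera adjusted p = 4.3e-05 and adjusted p = 0.493 with an estimated correlation and 0.203 with fry, over its alternatives 7.9e-07 to 0.493. Mitochondrial ribosomal genes differed by a median of -0.16 (camera adjusted p = 3.1e-13, adjusted p = 0.493 with an estimated correlation and 0.203 with fry), which was -0.02 (camera adjusted p = 0.419, over its alternatives 1.3e-21 to 0.493) without dDP untreated arrays 2 and 3. Altogether 38 probe sets differed, 21 higher and 17 lower (20 and 20 after quantile normalization), against 23 without wild type irradiated array 1 or wild type irradiated array 3 and 868 without dDP untreated array 1. The split was 408 and 460 without dDP untreated array 1 and 47 and 167 without arrays 2 and 3, so its direction hung on these arrays. The number was 214 without dDP untreated arrays 2 and 3, 433 with array weights and 20 with those 11 arrays alone.

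The de2f1 and wild type responses differed at 10 probe sets, all lower in de2f1 discs. The largest differences, each at 1 probe set chosen after its values were seen, were those of dysf (-4.48 ± 0.22) and ftz-f1 (-3.34 ± 0.37). The call of ftz-f1 was lost without wild type irradiated array 3 (adjusted p = 0.0624, over the arrays left out 0.00253 to 0.0624), and that of dysf held with any 1 array left out. At their representative probe sets 7 further genes passed, CG4962 (-2.02 ± 0.28), CG32313 (-1.24 ± 0.18), CG31601 (-1.08 ± 0.16), Ugt302K1 (-0.85 ± 0.13), Nepl3 (-0.80 ± 0.11), Ugt303A1 (-0.57 ± 0.08) and La (-0.45 ± 0.07) (limma interaction adjusted p of 0.0223 to 0.0435, n = 3 and 3 against 2 and 3). None of the 7 passed without wild type untreated array 2, wild type irradiated array 3, de2f1 untreated array 1 or 3 or de2f1 irradiated array 3, the lowest adjusted p without wild type irradiated array 3 being 0.175 and the range over their alternatives 9.8e-04 to 0.349. Fitting the 11 arrays of the 2 genotypes alone lost CG4962, CG31601, Ugt302K1, Nepl3, Ugt303A1 and La (adjusted p of 0.0539 to 0.076, over their alternatives 0.0025 to 0.349). With the replicate number as a block CG32313, CG31601, Ugt302K1, Nepl3, Ugt303A1 and La did not pass (adjusted p of 0.0684 to 0.0888, over their alternatives 9.8e-04 to 0.349). The Ugt303A1 means lay near the floor in all 6 groups (3.57 to 4.28), as did CG31601 in untreated and irradiated de2f1 discs (3.98 and 4.04) and CG32313 in untreated ones (4.58). CG31601 was also near it in untreated wild type discs (4.32), so the responses of CG31601 and Ugt303A1 in de2f1 discs could not be measured. After quantile normalization or with a robust prior La did not pass (adjusted p = 0.0661 and 0.06, over its alternatives 0.00691 to 0.349). The number of probe sets was 1 without wild type irradiated array 3, 2 without wild type untreated array 2 or de2f1 untreated array 1 or de2f1 untreated array 3 or de2f1 irradiated array 3, 3 without wild type untreated array 1 or wild type irradiated array 1, 4 without de2f1 irradiated array 1 or de2f1 irradiated array 2 and 6 without wild type untreated array 3, and 27 with array weights. G2 and M phase genes responded less negatively in de2f1 discs (median difference 0.17, no member passing in limma over all genes, 14 of 37 at an unadjusted p under 0.05, camera adjusted p = 1.7e-17, adjusted p = 0.208 with an estimated correlation and 0.103 with fry, over its alternatives 6.3e-19 to 0.208). The radiation response list differed by -0.23 (camera adjusted p = 1.9e-04, adjusted p = 0.962 with an estimated correlation and 0.955 with fry, over its alternatives 1.4e-05 to 0.962) and the ribosome biogenesis list by -0.15. The ribosome biogenesis list had camera adjusted p = 4.3e-09 and adjusted p = 0.208 with an estimated correlation and 0.103 with fry, over its alternatives 3.4e-10 to 0.208.

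Between the 2 mutants 22 probe sets responded differently, 12 higher and 10 lower in dDP discs, a split of 8 and 12 after quantile normalization, 631 and 653 without dDP untreated array 1 and 56 and 154 without arrays 2 and 3. dup (0.66 ± 0.08), CG33468 (1.00 ± 0.14) and CG32195 (0.65 ± 0.09) responded higher in dDP discs. CG5250 (-1.07 ± 0.12), spn-E (-1.07 ± 0.11), CG11125 (-1.02 ± 0.13), sofe (-0.72 ± 0.09) and CG4036 (-0.67 ± 0.09) responded lower (limma interaction adjusted p of 9.7e-04 to 0.0117, n = 3 in each of the 4 groups), and CG32195 did not pass after quantile normalization (adjusted p = 0.0601, over its alternatives 0.00507 to 0.0601). Cyp6a17 was called as well (-1.71 ± 0.17) but lay near the floor in dDP discs in both states (4.41 and 4.32), so its response there could not be measured. For Rchy1 the difference was -0.69 ± 0.10 (adjusted p = 0.0117), a call lost without de2f1 untreated array 1 (adjusted p = 0.0509, over its alternatives 0.00525 to 0.0521). For agt it was -1.0 ± 0.15 (adjusted p = 0.0183), lost without de2f1 untreated array 1 or 2, de2f1 irradiated array 2 or 3, dDP untreated array 2 or 3 or dDP irradiated array 1 or 3, and with the actin covariate or without dDP untreated arrays 2 and 3 together (0.0505 to 0.0539; highest adjusted p with 1 array left out = 0.0616, over its alternatives 0.00139 to 0.0736). With the 12 mutant arrays alone CG32195, Rchy1 and agt did not pass (adjusted p of 0.0521 to 0.0736, over their alternatives 0.00139 to 0.0736). The agt level was higher in dDP than in de2f1 discs in both states. It read 9.59 to 9.96 against 7.59 to 7.81 untreated and 11.46 to 11.76 against 10.37 to 10.58 irradiated. S phase genes differed by a median of 0.17. The S phase list gave camera adjusted p = 4.6e-10 and adjusted p = 0.742 with an estimated correlation and 0.238 with fry, over its alternatives 2.8e-13 to 0.742. The total was 14 without de2f1 untreated array 1 and 1284 without dDP untreated array 1, 210 without dDP untreated arrays 2 and 3, 1365 with array weights, 14 with those 12 arrays alone and 35 without the dimmest probe sets.

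Most genes that irradiation changed in wild type discs moved the same way in the mutants. Of the 846 probe sets called in wild type 803 had the same sign in dDP and 832 in de2f1 discs, and 527 and 372 passed there too. Those that rose did so by a median of 0.55 in wild type, 0.43 in dDP and 0.32 in de2f1 discs. The slope of the mutant on the wild type change was 0.628 (SD 0.107 over the 3 irradiated arrays) in dDP and 0.634 (SD 0.0248) in de2f1. These probe sets were chosen for their wild type change, which lowers such slopes, and over the probe sets called in each mutant the slopes were 0.88 and 0.787. Over the 14 genes of the radiation list they were 0.657 and 0.886.

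**Figure D2:**
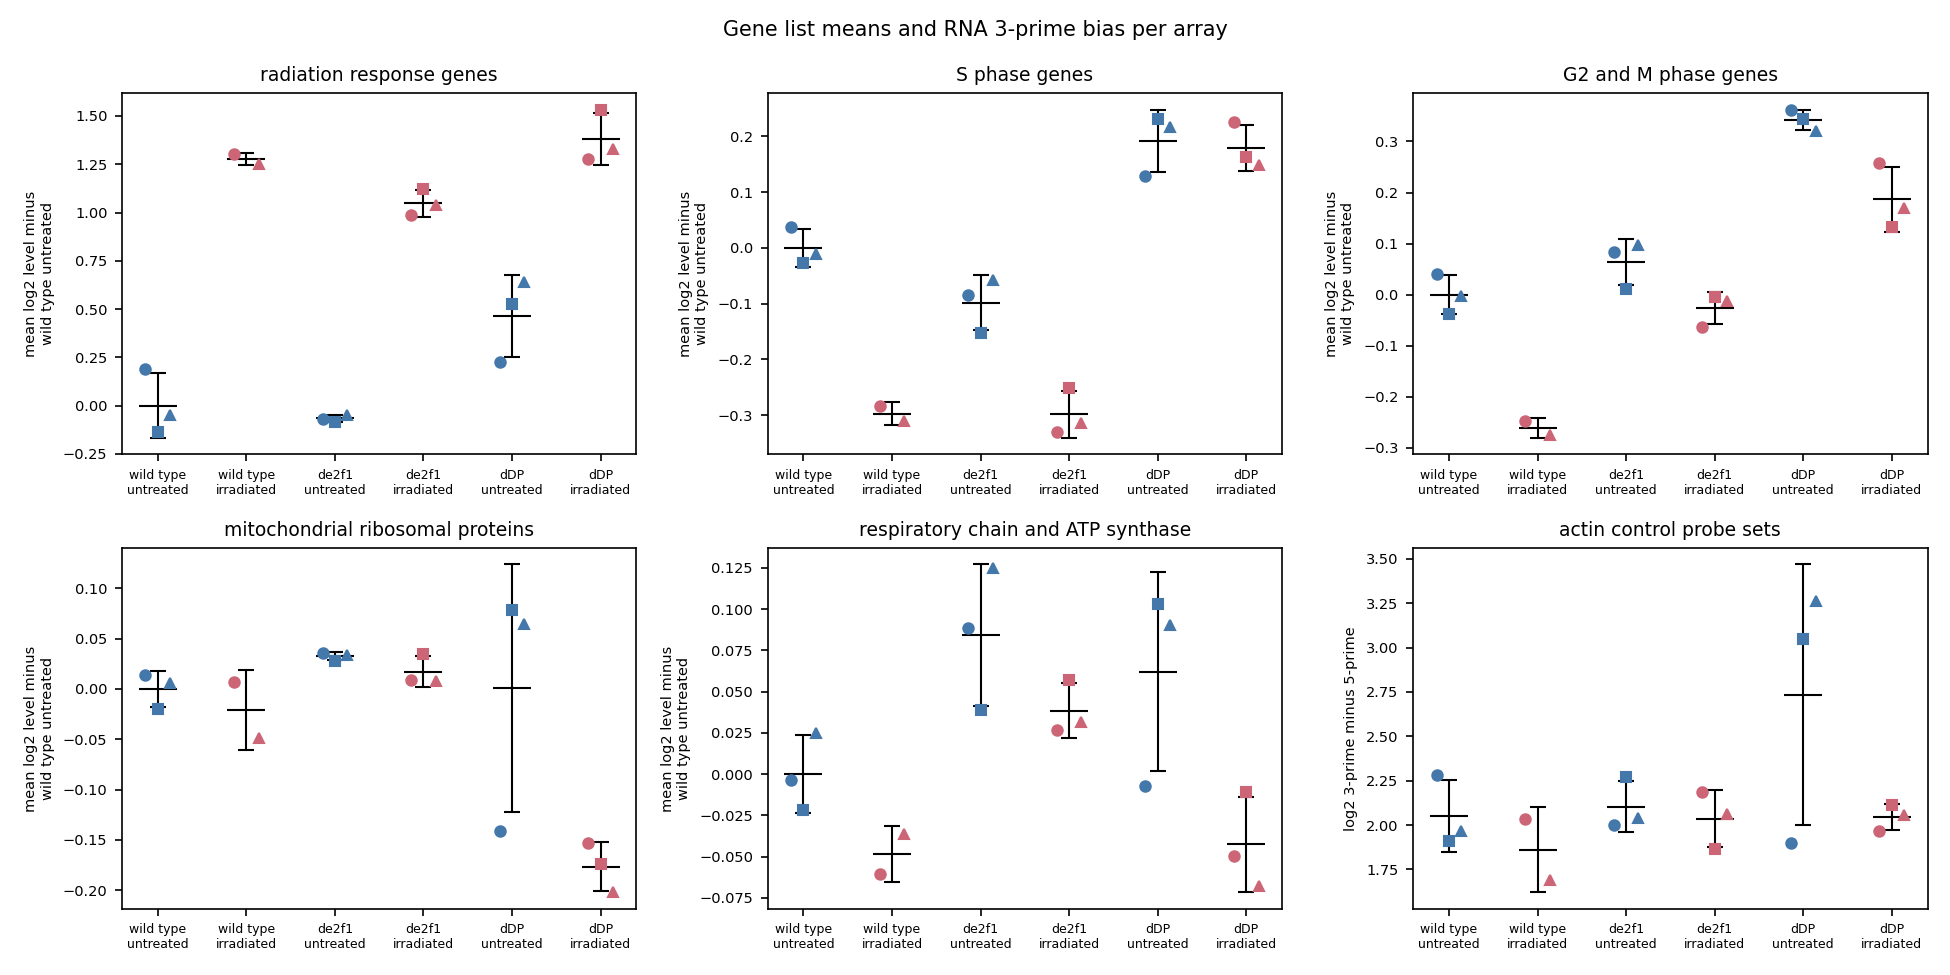
Mean log2 level of 5 gene lists relative to untreated wild type discs, and the actin 3-prime minus 5-prime difference, per array (points, shape by replicate number) with group mean ± SD (bars). The S phase list fell by a median of -0.31 in wild type and -0.20 in de2f1 discs against -0.03 in dDP discs, and the actin difference reached 3.26 on dDP untreated array 3.

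Without irradiation dDP discs differed from wild type in DNA repair, mitotic and germline genes. PCNA was lower by -0.64 ± 0.05 (n = 3 against 3), the crosslink repair genes FANCI (1.33 ± 0.09) and Fancd2 (1.18 ± 0.06) were higher, and the germline genes vas (4.18 ± 0.08), krimp (3.65 ± 0.13) and spn-E (2.65 ± 0.08) were far above wild type (limma, Benjamini-Hochberg adjusted p of 1.5e-13 to 3.4e-07). Large increases included CG10307 (5.58 ± 0.07), CG7997 (5.46 ± 0.18), Cubn2 (5.17 ± 0.52), CG7755 (4.94 ± 0.10) and Acbp6 (4.93 ± 0.62). Large decreases included those of the salivary glue genes Sgs7 (-7.44 ± 1.97) and Sgs4 (-7.24 ± 1.93), beside CG11854 (-5.33 ± 0.38) and Cyp6a17 (-5.01 ± 0.12), and salivary markers averaged 5.72 to 6.04 in untreated dDP against 10.08 to 12.61 in wild type samples. Near the floor were vas in wild type (4.53) and CG11854 and Cyp6a17 in dDP discs (4.48 and 4.41). Sgs7 and Sgs4 did not pass without dDP untreated arrays 2 and 3 (adjusted p = 0.084 and 0.102, over their alternatives 7.6e-04 to 0.102). In total 5261 probe sets differed, 2280 higher and 2981 lower (483 and 333 beyond 2-fold). CycE (-0.01) and skl (-0.21) did not pass, and grim was higher by 0.17 ± 0.06, a call lost without wild type untreated array 2 or 3 or dDP untreated array 1 or 2 (limma adjusted p = 0.157, 0.154, 0.0715 and 0.165, over its alternatives 0.00554 to 0.206). It was also lost with the 6 arrays fitted alone, the replicate block, the actin covariate, and without dDP untreated arrays 2 and 3 or array 1 and irradiated array 2 (adjusted p of 0.0552 to 0.206). The grim means of all 6 groups lay near the floor (3.54 to 3.97).

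Of 42 repair and checkpoint genes 23 were higher and 3 lower in untreated dDP discs (25 and 3 over the list alone), rad50 by 1.19 ± 0.07, with list median 0.37. Their repair list had camera adjusted p = 1.3e-07 and adjusted p = 0.386 with an estimated correlation. G2 and M phase genes were higher in 25 of 37 cases and lower in 3, including Ndc80 (0.82 ± 0.05), mad2 (0.80 ± 0.05) and Incenp (0.89 ± 0.06). The G2 and M phase list had a median of 0.33, camera adjusted p = 5.4e-09 and adjusted p = 0.325 with an estimated correlation. S phase genes were higher in 22 of 41 cases and lower in 5, with PolE2 (0.96 ± 0.06) and the primase gene Prim1 (1.11 ± 0.08) higher and the GINS gene Psf1 lower by -0.92 ± 0.06. The S phase list had a median of 0.21, camera adjusted p = 6.0e-04 and adjusted p = 0.756 with an estimated correlation. In the E2F and RB family Rbf2 was higher (0.88 ± 0.08) and the dREAM genes mip130 (-0.67 ± 0.11) and lin-52 (-0.47 ± 0.07) lower, as 2 of the 3 lower members beside 2 higher ones among 10 (camera adjusted p = 0.749). Radiation response genes such as Corp (1.46 ± 0.23), mre11 (1.30 ± 0.08), agt (1.36 ± 0.11) and Irbp (1.19 ± 0.13) were already higher, 7 of 14 in all with 1 lower (camera adjusted p = 0.00474, adjusted p = 0.8 with an estimated correlation, and 0.0661 without dDP untreated arrays 2 and 3, over its alternatives 9.4e-04 to 0.8). Cell death genes went both ways, 5 higher and 6 lower of 18, with Dronc (-0.87 ± 0.06) and Dark (-0.39 ± 0.06) lower (camera adjusted p = 0.925, fry adjusted p = 0.0267, over its alternatives 0.0267 to 0.99). The germline list had 9 of 18 higher and 2 lower (median 0.40, camera adjusted p = 6.0e-04, adjusted p = 0.294 with an estimated correlation), and its median was -0.02 over every probe set of the list.

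Injury signals and detoxification genes were also higher in untreated dDP discs. Ilp8, coding for a relaxin-like peptide released by damaged discs, was higher by 2.39 ± 0.27, the stress gene Gadd45 by 1.59 ± 0.21, the cytokine gene upd1 by 1.64 ± 0.26 and puc by 0.69 ± 0.08 (limma adjusted p of 9.6e-06 to 2.7e-04, n = 3 against 3). JNK and injury genes were higher in 8 of 15 cases and lower in 1 (camera adjusted p = 0.00474, adjusted p = 0.386 with an estimated correlation, and 0.06 over every probe set of the list, over its alternatives 8.0e-05 to 0.386). Detoxification genes were higher in 16 of 23 cases and lower in 1, for example GstD3 (1.75 ± 0.15), GstD9 (1.64 ± 0.16) and Cyp6a2 (1.30 ± 0.14) against catalase gene Cat (-0.71 ± 0.08). The detoxification list had a median of 0.80, camera adjusted p = 9.1e-06 and adjusted p = 0.325 with an estimated correlation. Immune genes DptB (1.13 ± 0.17), PGRP-SB1 (0.91 ± 0.14) and Rel (0.66 ± 0.07) and the chaperone cofactor gene stv (1.02 ± 0.11) were higher, 5 of 10 immune and 2 of 7 heat shock genes in all (camera adjusted p = 0.0706 and 0.435, the immune list passing without dDP untreated array 3 at 0.0469, over its alternatives 7.6e-05 to 0.325). Ecdysone-regulated genes were lower in 7 of 18 cases and higher in 2, with Eip78C (-2.58 ± 0.27), Hr4 (-1.81 ± 0.35) and Blimp-1 (-1.73 ± 0.32) lower and ftz-f1 (1.81 ± 0.19) higher (camera adjusted p = 0.305, passing over every probe set of the list at 0.0122, over its alternatives 0.0122 to 0.958). Hemocyte genes were lower in 10 of 13 cases and higher in 1, led by the prophenoloxidase genes PPO1 (-3.31 ± 0.40) and PPO2 (-2.95 ± 0.36) and by eater (-1.70 ± 0.28) (camera adjusted p = 0.00172, adjusted p = 0.609 with an estimated correlation). Hemocyte markers averaged 7.64 to 8.26 on the dDP arrays against 8.88 to 10.13 on the others.

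**Figure D3:**
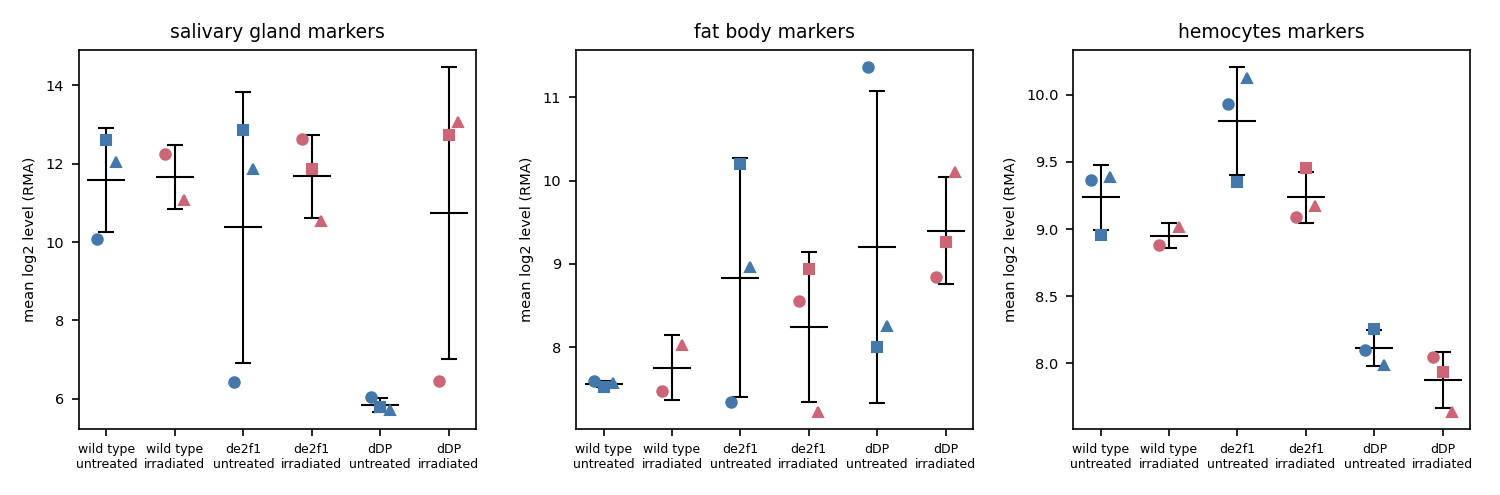
Mean log2 level (RMA) of salivary gland, fat body and hemocyte marker genes per array (points, shape by replicate number) with group mean ± SD (bars). Salivary gland markers averaged 5.72 to 6.04 in untreated dDP and 13.05 in irradiated dDP sample 3, and hemocyte markers stayed at or below 8.26 in all dDP samples.

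In untreated dDP discs, of the retinal determination genes 1 was higher (upd1) and 3 of 11 were lower, Optix by -0.44 ± 0.06. In the furrow list 3 of 12 were lower, the proneural gene ato by -0.45 ± 0.08, and in the photoreceptor list 3 of 21 were higher and 1 lower, with chp (1.10 ± 0.18) and sens (-0.58 ± 0.08) (limma adjusted p of 9.6e-05 to 5.0e-04). Camera adjusted p was 0.749, 0.749 and 0.414 for these 3 lists, and 0.0782 for the Notch targets, of which 3 of 9 were higher and which passed without dDP untreated array 1 (adjusted p = 0.0263, over its alternatives 0.0157 to 0.816) or after quantile normalization (0.0397). Mitochondrial ribosomal genes were higher in 14 and lower in 12 of 69 cases (camera adjusted p = 0.895, passing without dDP untreated array 1 at 0.0493 with a median of 0.07 against -0.0045 and without arrays 2 and 3 at 0.00165 with -0.15, over its alternatives 0.00165 to 0.958), and respiratory chain genes in 6 and 5 of 77 (adjusted p = 0.821). The paralogs COX7AL (3.47 ± 0.10) and ATPsynepsilonL (2.25 ± 0.12) were higher there, COX7AL from near the floor in wild type discs (4.08), and without such paralogs, a list made after the values were seen, 2 were higher and 3 lower of 55 (adjusted p = 0.925). Citric acid cycle genes were higher in 3 and lower in 3 of 14 cases, Idh3b by -1.10 ± 0.07, and mitochondrial biogenesis genes in 3 and 1 of 18 (camera adjusted p = 0.925 and 0.749). The ribosomal protein paralogs RpS19b (3.04 ± 0.16) and RpS5b (1.05 ± 0.16) were among 7 higher and 2 lower of 41 cytoplasmic ribosomal genes. Their list had a median of 0.04, camera adjusted p = 0.0465 and adjusted p = 0.824 with an estimated correlation. That call was lost without wild type untreated array 2 or 3 or dDP untreated array 2 or 3 (adjusted p = 0.0545, 0.0838, 0.0785 and 0.0915, over its alternatives 0.00302 to 0.824) and after quantile normalization (0.176). Ribosome biogenesis genes were higher in 2 and lower in 5 of 17 cases (camera adjusted p = 0.523).

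Markers of neighbouring tissues in untreated dDP discs gave 3 lower of 11 glial genes, repo by -1.27 ± 0.10, and 1 higher and 2 lower of 5 tracheal genes, the FGF receptor gene btl by -1.26 ± 0.12. Muscle markers were higher in 2 of 9 cases (Mlc2 0.87 ± 0.18), fat body markers in 1 of 8 (FASN1 0.81 ± 0.10), and peripodial, wing or antennal markers were lower in 2 of 10. Camera did not call these 5 lists (adjusted p of 0.15 to 0.925). Fry called glia and fat body (adjusted p = 0.00304 and 0.048), and camera fat body without dDP untreated arrays 2 and 3 (0.00188, over its alternatives 0.00188 to 0.816). No neuronal marker of the brain passed (limma, 0 of 9 at an unadjusted p under 0.05, camera adjusted p = 0.925). Salivary gland markers were lower in 6 of 8 cases with a median of -7.11 (camera adjusted p = 0.0465, lost without wild type untreated array 2 or 3 or any 1 dDP untreated array at 0.0608 to 0.0838, over its alternatives 0.0236 to 0.816, and adjusted p = 0.816 with an estimated correlation). Ring gland genes of steroid synthesis, a list made after the values were seen, were lower in 4 of 7 cases (camera adjusted p = 0.0288, 0.0737 without dDP untreated array 2 and 0.275 without arrays 2 and 3, over its alternatives 0.00745 to 0.783, and adjusted p = 0.783 with an estimated correlation). The male dosage compensation RNAs have no probe set of their own and were not analysed here.

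Untreated de2f1 discs differed less from wild type than dDP discs did. PCNA (-0.17 ± 0.05) did not pass (limma, Benjamini-Hochberg adjusted p = 0.0552, n = 3 against 3), and neither did CycE (0.11), skl (-0.16), grim (0.00) or Corp (-0.48). PCNA passed as lower with a trended prior, array weights, 1 probe set per gene, the actin covariate or without the dimmest probe sets (adjusted p of 0.00906 to 0.0426, over its alternatives 0.00906 to 0.15). Corp passed with the actin covariate (0.0442, over its alternatives 0.0442 to 0.545). The alkyl-repair gene agt was lower by -0.73 ± 0.11, the DNA end-repair gene gkt by -1.81 ± 0.07 and the helicase gene Fancm by -0.90 ± 0.13, and the piRNA pathway gene krimp was higher by 3.35 ± 0.13. Large increases that held with any 1 array left out included Cyp4p2 (5.15 ± 0.26), Rnf11 (3.97 ± 0.25), CG9150 (3.59 ± 0.17), Hsc70-2 (3.56 ± 0.09), CG32373 (3.47 ± 0.12), tut (3.18 ± 0.15) and CG8768 (3.09 ± 0.17), and such decreases CG15772 (-5.29 ± 0.25), CG6912 (-4.22 ± 0.29), Ir76a (-4.12 ± 0.08), CR44101 (-3.05 ± 0.27), CG9757 (-2.89 ± 0.42), CG8560 (-2.40 ± 0.17) and pirk (-2.20 ± 0.17) (adjusted p of 4.7e-13 to 5.1e-04). Hsc70-2 was near the floor in wild type (4.25) and CG15772 in de2f1 discs (4.40). In all 1688 probe sets differed, 731 higher and 957 lower (811 and 841 after quantile normalization). Repair and checkpoint genes were lower in 6 of 42 cases and higher in 2 (11 and 2 over the list alone) with median -0.10 (camera adjusted p = 0.00664, adjusted p = 0.891 with an estimated correlation and 0.0598 with fry), a call lost without de2f1 untreated array 2 (adjusted p = 0.0682) and after quantile normalization (adjusted p = 0.0651, over its alternatives 0.00266 to 0.891). S phase genes were lower in 8 of 41 cases and higher in 2, as for Psf1 (-0.51 ± 0.06), Mcm10 (-0.48 ± 0.08) and PolA2 (-0.31 ± 0.06) against Prim2 (0.43 ± 0.07), and their camera call (adjusted p = 0.0339, adjusted p = 0.891 with an estimated correlation and 0.155 with fry) was lost without wild type untreated array 1 (0.111) or de2f1 untreated array 2 (0.155, over its alternatives 0.0148 to 0.891) or after quantile normalization (0.143). The mitotic genes aurB (0.48 ± 0.06) and Mis12 (0.70 ± 0.11) were higher. The caspase genes Dronc (-0.52 ± 0.06) and Dredd (-0.27 ± 0.05) and the immune genes CecB (-1.85 ± 0.35) and PGRP-LB (-1.10 ± 0.12) were lower. Respiratory chain genes had a median of 0.07, 3 of 77 being higher, ATPsynepsilonL by 1.61 ± 0.12. The respiratory chain list had camera adjusted p = 5.5e-04 and adjusted p = 0.891 with an estimated correlation and 0.122 with fry, over its alternatives 1.8e-05 to 0.891. Hemocyte genes were higher in 3 of 13 cases (6 over the list alone), NimC1 by 1.74 ± 0.27. The hemocyte list gave camera adjusted p = 0.0059 and adjusted p = 0.891 with an estimated correlation and 0.0851 with fry, over its alternatives 2.2e-05 to 0.891.

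The 2 mutants shared 455 probe sets higher and 652 lower than in untreated wild type discs, where independence would give 88.8 and 152, and 109 went opposite ways. Both comparisons used the same 3 wild type arrays. In 50 simulations of the shared controls without any effect the highest numbers were 0 and 1. With no effect simulated few probe sets can pass, so these numbers do not show what the shared arrays add to the overlap. The mean simulated correlation of the changes was 0.512 against 0.493 observed, and the covariance 0.0174 against 0.0853. CG15772 was near the floor in de2f1 discs (4.40). No split of 3 controls leaves 2 for each mutant, so part of the excess may come from the shared controls. Genes lower in both included CG15772 (-4.57 and -5.29), Ir76a (-4.19 and -4.12), lin-52 (-0.47 and -0.75), Psf1 and Dronc, and genes higher in both included krimp, RpS19b (3.04 and 1.71) and mre11 (1.30 and 0.41).

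Against de2f1 discs, untreated dDP discs were higher in repair, radiation response and injury genes. agt was higher by 2.09 ± 0.11, Corp by 1.95 ± 0.23, Ilp8 by 2.86 ± 0.27 and Gadd45 by 2.36 ± 0.21 (n = 3 against 3), and PCNA was lower by -0.48 ± 0.05 (limma, Benjamini-Hochberg adjusted p of 8.6e-09 to 3.4e-05). Repair and checkpoint genes were higher in 29 of 42 cases and lower in 1 (33 and 1 over the list alone), among them FANCI (1.33 ± 0.09), rad50 (1.27 ± 0.07) and Fancd2 (1.16 ± 0.06). The repair and checkpoint list had a median of 0.49, camera adjusted p = 6.1e-16 and adjusted p = 0.162 with an estimated correlation. S phase genes were higher in 23 of 41 cases and lower in 3, with Prim1 (1.16 ± 0.08), PolE2 (1.03 ± 0.06) and PolA2 (0.81 ± 0.06), and mitotic genes in 23 and 4 of 37, with cid (1.33 ± 0.09), Ndc80 (0.79 ± 0.05) and Nuf2 (0.79 ± 0.05) (camera adjusted p = 4.5e-07 and 2.4e-07, adjusted p = 0.331 and 0.305 with an estimated correlation). Radiation response genes were higher in 7 of 14 cases and lower in 2 (8 and 2 over the list alone), with median 0.44. The radiation response list had camera adjusted p = 0.00177 and adjusted p = 0.683 with an estimated correlation. JNK and injury genes were higher in 9 of 15 cases, detoxification genes in 14 of 23 (GstD5 2.83 ± 0.31) and immune genes in 6 of 10 (camera adjusted p = 6.2e-05, 3.9e-06 and 0.00177, adjusted p = 0.162, 0.18 and 0.111 with an estimated correlation). The germline genes vas (4.19 ± 0.08), spn-E (2.99 ± 0.08) and Phf7 (1.88 ± 0.09) were higher. Hemocyte genes were lower in 11 of 13 cases, PPO1 (-4.31 ± 0.40), PPO2 (-4.09 ± 0.36), He (-2.03 ± 0.28) and Pxn (-1.54 ± 0.21) (camera adjusted p = 2.4e-07, adjusted p = 0.18 with an estimated correlation), as was the steroid synthesis gene spok (-3.80 ± 0.58). Other large differences were CG10307 (5.45 ± 0.07), CG7755 (4.95 ± 0.10), Acbp6 (4.94 ± 0.62), CG11854 (-4.07 ± 0.38), Cyp6a17 (-3.88 ± 0.12) and Zip102B (-3.80 ± 0.16). Near the floor were vas (4.52) and GstD5 (4.29) in de2f1 and CG11854 (4.48) and Cyp6a17 (4.41) in dDP discs. CycE, skl and grim did not pass (-0.12, -0.06 and 0.17), though CycE passed without dDP untreated array 1 (limma adjusted p = 0.0328), the same without irradiated array 2 as well (0.00368) or with array weights (0.0315, over its alternatives 0.00368 to 0.931) and grim without dDP untreated array 3 (0.038) or with a trended prior, array weights or 1 probe set per gene (0.0104 to 0.0434, over its alternatives 0.0104 to 0.198). In all 4184 probe sets differed, 1952 higher and 2232 lower, and 2360 did with the 6 arrays fitted alone.

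After irradiation dDP discs differed from wild type in cell cycle, repair and germline genes. S phase genes were higher in 29 of 41 cases and lower in 3 (median 0.55 against 0.21 in untreated discs), as for Prim1 (1.70 ± 0.09), PolE2 (1.44 ± 0.06), PolE1 (1.35 ± 0.08) and dup (0.91 ± 0.06) (n = 3 against 2). G2 and M phase genes were higher in 27 of 37 cases and lower in 1, as for aurB (1.06 ± 0.07) and fzy (1.01 ± 0.06), and repair genes were higher in 19 of 42 and lower in 2, FANCI (1.54 ± 0.10), Fancd2 (1.35 ± 0.07) and tefu (1.00 ± 0.07) against gkt (-1.14 ± 0.08). Camera adjusted p was 2.9e-14, 3.3e-14 and 1.4e-06, and adjusted p = 0.181, 0.181 and 0.384 with an estimated correlation. Notch targets of the E(spl) complex were higher in 7 of 9 cases (camera adjusted p = 2.0e-04, adjusted p = 0.352 with an estimated correlation), and mitochondrial ribosomal genes were lower in 28 of 69 cases and higher in 2, mRpL2 by -0.65 ± 0.06. The mitochondrial ribosomal list gave camera adjusted p = 5.4e-04 and adjusted p = 0.763 with an estimated correlation. Germline genes were higher in 9 of 18 cases and lower in 2, vas (4.48 ± 0.09) and krimp (3.76 ± 0.14). The germline list had camera adjusted p = 1.4e-05 and adjusted p = 0.0856 with an estimated correlation. The death gene grim (0.37 ± 0.07, near the floor at 3.97 against 3.60), Ilp8 (2.84 ± 0.30), Ets21C (1.46 ± 0.31) and GstE7 (2.77 ± 0.37) were higher, and the hemocyte genes PPO1 (-2.97 ± 0.45) and PPO2 (-2.55 ± 0.40) lower (limma adjusted p of 9.3e-06 to 0.00285). Large differences included Cyp4p2 (5.98 ± 0.29), Cubn2 (5.76 ± 0.58), CG7997 (5.65 ± 0.20), CG10307 (5.11 ± 0.08), Cyp6a17 (-6.43 ± 0.14) and Zip102B (-4.52 ± 0.18). Near the floor were vas (4.56) and Cubn2 (4.22) in wild type and Cyp6a17 (4.32) in dDP discs. PCNA was lower by -0.20 ± 0.06, a call lost without wild type irradiated array 1 or 3 or dDP irradiated array 3 (limma adjusted p = 0.136, 0.0548 and 0.0516, over its alternatives 0.00415 to 0.136) after quantile normalization (0.066) and with the 5 arrays fitted alone (0.0765). CycE (0.15), skl (0.43) and Corp (0.53) did not pass. With the 5 arrays fitted alone skl passed (adjusted p = 0.00837, over its alternatives 0.00837 to 0.813), and without dDP untreated array 1 and irradiated array 2 CycE passed (0.24, 0.00652, over its alternatives 0.00652 to 0.715). In total 4355 probe sets differed, 1908 higher and 2447 lower.

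Irradiated de2f1 discs had higher mitotic genes than irradiated wild type discs: 18 of 37 were higher (22 over the list alone), with aurB (0.89 ± 0.07), Mis12 (0.85 ± 0.12), Incenp (0.47 ± 0.07) and fzy (0.46 ± 0.06) (n = 3 against 2, median 0.21, camera adjusted p = 2.4e-12, adjusted p = 0.649 with an estimated correlation). Repair and checkpoint genes were lower in 13 of 42 cases and higher in 1, with gkt (-1.88 ± 0.08) and Fancm (-1.06 ± 0.14) against the checkpoint kinase gene lok (0.45 ± 0.06). The repair and checkpoint list gave camera adjusted p = 1.7e-04 and adjusted p = 0.898 with an estimated correlation. In the radiation response list 5 of 14 were lower and 1 higher (camera adjusted p = 0.0357, adjusted p = 0.898 with an estimated correlation and 0.147 with fry), a call lost without wild type irradiated array 1 (adjusted p = 0.0962) or de2f1 irradiated array 1 (0.0608, over its alternatives 0.0126 to 0.898). RnrL (-0.50 ± 0.07), Dronc (-0.64 ± 0.07), lin-52 (-0.76 ± 0.08), RPA3 (-0.65 ± 0.10) and Psf1 (-0.55 ± 0.07) were lower, and dpa (0.45 ± 0.06) and krimp (3.28 ± 0.14) higher (limma, Benjamini-Hochberg adjusted p of 4.8e-09 to 5.2e-04). Ribosome biogenesis genes were lower in 2 of 17 cases. The ribosome biogenesis list had camera adjusted p = 0.00214 and adjusted p = 0.898 with an estimated correlation. Large differences included Cyp4p2 (6.15 ± 0.29), Cyp4p1 (4.48 ± 0.27), Rnf11 (3.73 ± 0.28), Hsc70-2 (3.64 ± 0.11), CG15772 (-5.23 ± 0.28), Ir76a (-4.47 ± 0.09) and CG6912 (-3.86 ± 0.32). Hsc70-2 (4.45) was near the floor in wild type and CG15772 (4.23) and Ir76a (4.57) in de2f1 discs. PCNA, CycE, skl, grim, Dp and Corp did not pass (-0.04, 0.19, 0.00, -0.06, 0.07 and -0.16). In total 1619 probe sets differed, 691 higher and 928 lower, a split that turned to 810 and 780 after quantile normalization, with 933 without wild type irradiated array 1, 737 without array 3 and 2781 with array weights.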

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

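Of the tests in this part, those with the actin difference as a covariate, of dividing cells, of genotype carried over between splits, of the mitochondrial ribosomal fall against untreated array 1 and of a differing response were chosen after the result was seen. A result is listed here because a limma interaction tested whether irradiation acted differently in 2 genotypes. The dDP and wild type responses differed at 38 probe sets, including dup (0.79), dpa (0.69), timeout (0.81), PCNA (0.44), Osi4 (1.33), CG9752 (0.74), mre11 (-1.04), spn-E (-1.02), CG4962 (-2.10), CG32313 (-1.41) and CG5250 (-1.10). The de2f1 and wild type responses differed at 10, including CG4962 (-2.02), CG32313 (-1.24), Ugt302K1 (-0.85), Nepl3 (-0.80) and La (-0.45), while CG31601 (-1.08) and Ugt303A1 (-0.57) were called with de2f1 discs near the floor. The responses of the 2 mutants differed at 22, including dup (0.66), CG33468 (1.00), CG32195 (0.65), CG5250 (-1.07), spn-E (-1.07), CG11125 (-1.02), agt (-1.0), sofe (-0.72), Rchy1 (-0.69) and CG4036 (-0.67). Cyp6a17 was called against wild type (-1.42) and de2f1 (-1.71), but lay near the floor in dDP discs (4.41 and 4.32), so its response there could not be measured.

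The S phase list fell after irradiation in wild type and not in dDP discs. A 3-prime bias of dDP untreated arrays 2 and 3 would need this difference to shrink with the actin difference of each array as a covariate, where its median was 0.324 (camera adjusted p = 8.1e-25, over its alternatives 8.1e-25 to 0.196), and 0.239 to 0.349 with any 1 array left out. Salivary gland RNA would need it to shrink with the salivary score of each array as a covariate, where it was 0.356 (camera adjusted p = 1.3e-19). A smaller loss of dividing cells alike in all phases may move G2 and M genes as much. Their median difference was 0.0908, below the S phase one by 0.234 (0.182 to 0.249 with any 1 array left out). Such a loss stays open, as equal shifts and loss or arrest by phase were untested. Also open is that S phase genes may fall only where Dp is present. This idea came from the same arrays and had no test of its own.

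Mitochondrial ribosomal genes fell after irradiation in dDP discs, where untreated arrays 2 and 3 had larger 3-prime to 5-prime control differences than array 1. The median was -0.1002 with the actin difference of each array as a covariate (camera adjusted p = 2.6e-05, over its alternatives 1.0e-18 to 0.572). It was -0.24 to -0.0861 with any 1 array left out. This test leans on array 1 and cannot decide. Salivary gland RNA alone is argued against by -0.158 with its score as a covariate (camera adjusted p = 1.1e-10). Against untreated array 1 alone the median change was -0.0461, with 47 of 69 members below 0 against 66 and 66 for arrays 2 and 3, but array 1 also stood apart in its fat body markers (11.36 against at most 8.26 on the other 2) and in its mean correlation with its group (0.983). The median difference of these genes between untreated arrays 2 and 3 and array 1 was 0.219, inside the central 95% of 10000 random lists matched on gene length and level (0.129 to 0.225), so a loss that depends on gene length could account for that gap. A bias as part or all of the fall and a response that differs between dDP and wild type discs cannot be told apart. The median difference in response without arrays 2 and 3 was -0.021. That value and the change against array 1 rest on a single untreated dDP array.

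Other splits of the same samples were run for comparisons with 3 arrays or more per group. For irradiation within dDP discs 1 of 10 splits, the real one, gave 1659 calls and the highest other 296. Within de2f1 discs it was 1 of 10, with 431 calls against 3. For the 3 untreated genotype comparisons the real split gave 5261, 1688 and 4184 calls, 1 of 10 splits each time, and limma called 0 probe sets in each of the other splits. With 3 against 3 arrays the splits are too few for a share under 0.05. For the difference in response between dDP and de2f1 discs 11 of 100 drawn splits gave 22 calls or more, the highest other 2371. Of the 10 others 10 grouped unequal numbers of dDP arrays in the 2 treatments, which carries the genotype difference into the difference in response. These splits therefore do not show whether chance can be excluded.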

How the results depend on the processing

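The alternatives without dDP untreated arrays 2 and 3, without dDP untreated array 1 and irradiated array 2, with the actin difference as a covariate and with the respiratory chain list without paralogs were chosen after the data were seen, and the others before the data were examined. With array weights the number of changed probe sets was 1317 in wild type, 1039 in de2f1 and 3851 in dDP discs after irradiation, 2781 for irradiated de2f1 against wild type discs, and 433, 27 and 1365 for the differences in response (dDP against wild type, de2f1 against wild type, dDP against de2f1). Fitting the arrays of a comparison alone gave 242 for irradiated dDP discs, 2360 for untreated dDP against de2f1 discs and 20 and 14 for the dDP responses against wild type and de2f1. Without the dimmest probe sets the dDP and de2f1 responses differed at 35. Without dDP untreated arrays 2 and 3 the dDP irradiation count was 1060 and the differences of its response 214 and 210, and without dDP untreated array 1 and irradiated array 2 they were 3496, 1175 and 1349. The cause of these shifts was not tested.

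Leaving out 1 array of the comparison at a time moved the counts from 389 to 687 (wild type irradiation), 268 to 344 (de2f1), 962 to 3849 (dDP), 4375 to 6011, 1158 to 1324 and 3172 to 4982 (untreated dDP and de2f1 against wild type and dDP against de2f1), 2904 to 3983 and 737 to 1281 (irradiated dDP and de2f1 against wild type) and 23 to 868, 1 to 8 and 14 to 1284 (differences in response as ordered above). Without dDP untreated array 1, the comparisons it is not part of gave 1116, 600, 2175, 5027, 2136 and 14 in that order, through the variance common to all arrays. Where 1 irradiated wild type array was left out, the lone remaining array was assumed to vary like the other groups. The probe sets shared by both mutants ranged over 316 to 577 higher and 435 to 785 lower. List medians ranged over 1.29 to 1.40, 0.96 to 1.07 and 0.87 to 1.02 for radiation response genes and -0.35 to -0.29, -0.24 to -0.17 and -0.07 to -0.01 for S phase genes (wild type, de2f1 and dDP irradiation), 0.25 to 0.33 for the S phase difference, -0.25 to -0.14 for mitochondrial ribosomal genes in dDP, 0.33 to 0.43 and 0.47 to 0.53 for repair genes and 0.30 to 0.37 for mitotic genes in untreated dDP discs, and 0.21 to 0.24 for mitotic genes in irradiated de2f1 discs. The response slope ranged over 0.563 to 0.674 in dDP and 0.582 to 0.65 in de2f1 discs, was 0.88 and 0.787 over probe sets called in the mutant, 0.886 for de2f1 over the radiation list and 0.736 for dDP without untreated arrays 2 and 3.

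Estimating the correlation within lists ended the camera calls with the medians unchanged: radiation response in wild type (1.35, adjusted p = 0.0617) and dDP (0.96, 0.104) and in untreated dDP against de2f1 (0.44, 0.683), S phase in wild type (-0.31, 0.0884) and de2f1 (-0.20, 0.171) and for the difference in response (0.32, 0.196), mitochondrial ribosomal in dDP (-0.19, 0.572), repair in dDP against wild type (0.37, 0.386) and de2f1 (0.49, 0.162), and mitotic genes in dDP (0.33, 0.325) and irradiated de2f1 discs (0.21, 0.649). The radiation list in de2f1 discs passed with it (0.0236). List medians changed sign for cell death in wild type discs (0.0236 and 0.0327 without untreated array 1 or 2, lowest -0.0619 without irradiated array 1, 0.0463 over every probe set of the list) and in de2f1 discs (-8.0e-04 without irradiated array 2, highest 0.0933 without untreated array 3), for mitochondrial ribosomal genes in untreated dDP discs (0.0742 without array 1, lowest -0.0493 without array 2) and for germline genes there (-0.0224 over every probe set of the list). Among the other settings of gene lists 1193 gave the reported call, 116 lost it and 18 gained one, and for named genes the numbers were 5486, 140 and 22.

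The replicate block moved the de2f1 and wild type difference in response to 3 probe sets and left the other counts within 1.5 times (766, 373 and 1376 for irradiation in wild type, de2f1 and dDP discs). Replicate numbers did not pair the samples: of 21 pairs of same-numbered arrays 4 had deviations from their group means that correlated above 0.1, in a range of -0.395 to 0.376.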

Other observations

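Both tests in this part that bear on the large shared changes were chosen after the result was seen, as were the probe sets of dysf and ftz-f1 named here. In irradiated wild type discs 1 probe set of the PAS-domain transcription factor gene dysf rose by 4.25 ± 0.17 from log2 5.42 to 9.66 (limma adjusted p = 1.4e-08, n = 2 against 3). Neither mutant followed (differences in response of -4.22 ± 0.22 in dDP and -4.48 ± 0.22 in de2f1 discs). Its other 2 probe sets did not pass in wild type discs (0.11 ± 0.09 and 0.23 ± 0.10). The nuclear receptor gene ftz-f1 behaved alike. Of its 2 probe sets 1 rose by 3.50 ± 0.28 in wild type discs (limma adjusted p = 2.8e-06, differences in response of -3.38 ± 0.37 and -3.34 ± 0.37), while the other, more strongly expressed probe set did not pass (0.27 ± 0.21).

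In untreated discs 33 probe sets differed from wild type by at least log2 2 in both mutants, in the same direction. Of these 21 were higher and 12 lower, and 23 carry the symbol of 1 gene each, 23 genes in all. Decreases included those of RFeSP, coding for the Rieske iron-sulfur protein of the respiratory chain (-5.80 and -5.59 in dDP and de2f1 discs), CG15772 (-4.57 and -5.29, with de2f1 discs near the floor at 4.40), Ir76a (-4.19 and -4.12) and 1 probe set of gkt (-3.89 and -4.04). Increases included the cytochrome P450 genes Cyp4p2 (4.59 and 5.15) and Cyp4p1 (3.56 and 3.07), the gustatory receptor genes Gr64a (2.42 and 2.44) and Gr61a (3.62 and 2.06), the ion channel gene rpk (3.24 and 2.63), fuss (2.62 and 2.41) and BckdhB (2.40 and 2.35).

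A strain variant under the probes could give such large shared changes. Of 2 well expressed other probe sets of the same genes 1 moved by less than 0.5 in both mutants (RFeSP, -0.02 and 0.14), while that of gkt fell with the first (-1.02 and -1.81). Loss of E2F activity from the posterior alone in de2f1 discs would leave smaller falls there than in dDP discs, and the median ratio of the de2f1 to the dDP fall was 0.983 (quartiles 0.949 and 1.06). Choosing probe sets that changed in both mutants favours ratios near 1, and over all 65 probe sets that fell by at least 2 in dDP discs the median ratio was 0.343, so strain and E2F effects cannot be told apart with 2 such probe sets and this choice.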
